A study of Rattus norvegicus with 42 samples.

How the data were processed

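Gene expression was measured in rat metanephric mesenchyme, dissected at embryonic day 13.5 and separated from the ureteric bud. There were 42 arrays (Affymetrix rat expression arrays) in 21 groups of 2 biological replicates. The groups were fresh tissue, culture without inducer for 1 and 2 days, and culture with LIF, NGAL or the ANX fraction taken on each of days 1 to 5 and on day 7. Per the labels, the medium of all cultures held insulin, transferrin, selenium, dexamethasone, prostaglandin, T3, an FGF and a TGF, and explants grew on collagen-coated filters. What the ANX fraction contains is not given in the sources used here.

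The deposited values are in the unit intensity, from the robust multichip analysis (RMA) that the authors name in the series design and the processing notes, without a version. The values ran from 7.6 to 17972 with array medians of 83.3 to 88.4, so they are on a linear scale, and log2 was taken before any test. The platform's table, joined to a table of RefSeq genes by gene number, gave 1 gene to 20832 of 31099 probe sets (14218 genes); 436 named several genes and 9831 none. Each gene was represented by its probe set with the highest mean. A gene was tested when its highest group mean exceeded the 40th percentile of all values (log2 5.79, intensity 55.2), which left 11387 genes, 95 of them on probe sets that can bind related transcripts. For arrays there is no read depth; this threshold stands for signal over background, and genes past it are called measured. Of 487 named changes 170 had a group mean below it; beside these a floored value is the change with such means set to the threshold.

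Genes were compared with R 4.3.3 and limma 3.58.1 by a linear model with a mean per group over all 42 arrays (21 residual degrees of freedom) and empirical Bayes variances with a trend. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Comparisons were uninduced days 1 and 2 against fresh, each inducer against control as the mean of days 1 and 2, each inducer's day 7 against day 1, each pair of inducers as the mean of 6 days, and a moderated F-test of inducer by day. Fold changes are on the log2 scale with the model's standard error (SE). Replicate numbers were not taken as pairs. On simulated data with 200 changed genes, 56.7% of log2 shifts of 0.5 and 94.0% of shifts of 1 were recovered for inducer against control, 23.9% and 77.6% for day 7 against day 1, and 82.1% and 97.0% for inducer against inducer, with 8, 6 and 12 false calls. The simulated noise was independent between genes and arrays. It held no shift of whole arrays in RNA or labelling, so these rates may be better than those in the real data.

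There were 25 gene lists: nephron progenitor, early nephron induction, epithelial junction and keratin, proximal tubule, loop of Henle and distal tubule, podocyte, proliferation, p53 targets, LIF and STAT3 response, iron handling, Wnt/beta-catenin targets, FGF and MAPK response, TGF-beta targets, glucocorticoid targets, hypoxia and glycolysis, cholesterol synthesis and interferon response. Lists of other cell types were renal stroma, ureteric bud and collecting duct, endothelium, macrophage and leukocyte, erythroid, neuron and Schwann cell, skeletal muscle, and cartilage. Of 490 members 355 were measured. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all lists and 11 comparisons; this test asks whether a list moved relative to the other genes. Its result with an estimated correlation is printed beside each call, and no list was called that way in any comparison (0 of 93 calls; lowest adjusted p 0.227). The self-contained test is limma's fry. A list score is the mean log2 level of the measured members over fresh tissue, and the arrays in the called direction are those of the first group beyond the mean of the other group on the same day.

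The comparisons, lists, thresholds and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 6 genes with the largest rise and the 6 with the largest fall among called genes whose replicates did not overlap (or with the same sign on every day averaged); 10 anchor genes, of which Six2 and Cited1 had no probe set of a single gene and Cdh6 lay below the threshold; and up to 4 members with the smallest adjusted p of each list called. Not every gene the rule took is printed. Levels of genes on particular days, and genes of the F-test, were singled out after their values were seen.

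Alternatives were no filter and a stricter filter (60th percentile, log2 7.10), quantile normalization again, the mean of a gene's probe sets, all probe sets, a 2-fold minimum, no variance trend, array weights, only the arrays compared, a replicate block, each array left out in turn, single days or other sets of days, split controls, and for lists the estimated correlation and fry. Arrays differed in the log2 3'/5' ratio of the dap spike-in (0.77 to 2.35, with 12 arrays at or above 1.6), which correlated over arrays with that of actin (r = 0.926) and of GAPDH (r = 0.910; p = 0.0001 each, the smallest the 10000 permutations can give). Within groups 3338 genes went with this ratio. Hence a fit with the ratio as covariate and a fit of the arrays under 1.6 were added, and list calls and scores were repeated with each array left out, all chosen after seeing the data. In fits that left a group with 1 array, the lone array was assumed to vary like the other groups. Probe sets without a single gene were left out of the comparisons because they cannot be named; raw array files were not used here.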

Results

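Mesenchyme cultured without inducer for 1 day had lower early nephron induction, erythroid and glycolysis genes than fresh tissue, and higher cholesterol synthesis genes. Relative to fresh tissue (2 arrays against 2), Fosb and Fos, immediate early transcription factors, fell by 5.06 (SE 0.20, floored -3.72) and by 3.15 (SE 0.32) on the log2 scale. Floored values set group means below the signal threshold of log2 5.79 to it, and are given where a group lay below it. Fst, the activin-binding protein follistatin, changed by -3.28 (SE 0.54), while Mgp, a matrix Gla protein, rose by 4.39 (SE 0.55), Ifitm1 by 3.85 (SE 0.67), Gbp2, an interferon-induced GTPase, by 3.52 (SE 0.56, floored 2.20) and S100a6 by 3.35 (SE 0.59). Of 12 measured early nephron induction genes 3 fell, Pax8, Lef1 and Ccnd1 (5 fell adjusted over the list alone), with a median of -0.80. This list had adjusted p = 0.00102, and adjusted p = 0.322 with an estimated correlation, and the list score was lower in 2 of 2 cultured arrays. The single calls of Pax8 (-1.74, SE 0.44) and Ccnd1 (-3.05, SE 0.81) ended whichever of the 4 arrays was left out, and that of Lef1 for 3 of them (highest adjusted p 0.140, 0.150 and 0.188). Erythroid genes were lower, with 4 of 9 fallen (6 adjusted over the list alone), among them Hbg1 (-2.94, SE 0.51) and Ahsp, the alpha-globin chaperone (-1.36, SE 0.24). The list test gave adjusted p = 6.05e-06, and adjusted p = 0.227 with an estimated correlation. In the hypoxia and glycolysis list 8 of 22 members fell and 1 rose (12 and 1 adjusted over the list alone), led by Ldha, lactate dehydrogenase A (-1.21, SE 0.17), with a median of -0.57. As a list they had adjusted p = 6.02e-05, and adjusted p = 0.309 with an estimated correlation. In all, 690 of 11387 genes were called, 433 higher and 257 lower. The count was 180 without fresh replicate 1, 206 without fresh replicate 2 and 184 without day 1 control replicate 1, and 89 in arrays with a low spike-in 3'/5' ratio.

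Of the remaining lists called after 1 uninduced day, cholesterol synthesis was higher, with 2 of 12 members risen (7 adjusted over the list alone), a median of 0.70, adjusted p = 0.000181 and adjusted p = 0.415 with an estimated correlation. Wnt/beta-catenin targets were lower, with 4 of 11 fallen (4 adjusted over the list alone), a median of -0.45, adjusted p = 0.00236 and adjusted p = 0.227 with an estimated correlation. Lef1 and Ccnd1 are in this list too. Proliferation genes were lower, with 2 of 24 fallen (6 adjusted over the list alone), a median of -0.28, adjusted p = 5.17e-05 and adjusted p = 0.553 with an estimated correlation. Endothelial genes were lower, with 2 of 16 fallen (4 adjusted over the list alone). Tested together, they had adjusted p = 0.0312, and adjusted p = 0.558 with an estimated correlation. The self-contained test gave no call for the last pair of lists (adjusted p 0.0904 for proliferation and 0.0995 for endothelium), and the endothelial call also ended with the stricter filter (adjusted p = 0.116) and after quantile normalization (0.0504). It ended as well without fresh replicate 2 (adjusted p = 0.0654) and without day 1 control replicate 2 (0.422), where the score difference went from -0.23 to -0.07, and it was -0.39 without day 1 control replicate 1.

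After 2 days without inducer Mgp rose by 5.90 (SE 0.55), S100a6 by 4.73 (SE 0.59), Ifitm1 by 4.64 (SE 0.67) and Gbp2 by 4.61 (SE 0.56, floored 3.29), and Fosb fell by 4.92 (SE 0.20, floored -3.72) on the log2 scale. Proliferation genes were lower, with 20 of 24 fallen (22 adjusted over the list alone), such as Birc5, survivin (-0.88, SE 0.16), and the spindle checkpoint kinase gene Bub1 (-1.08, SE 0.21), with a median of -0.77. For the whole list limma gave adjusted p = 9.45e-10, and adjusted p = 0.345 with an estimated correlation. Endothelial genes were lower, with 9 of 16 fallen (10 fallen and 1 risen adjusted over the list alone), including Ramp2 (-1.75, SE 0.28) and the VEGF receptor gene Kdr (-1.66, SE 0.39). Camera gave the list adjusted p = 0.000553, and adjusted p = 0.346 with an estimated correlation. Erythroid genes were lower, with 7 of 9 fallen (9 adjusted over the list alone), Hbg1 by -3.43 (SE 0.51). At the list level this was adjusted p = 6.02e-05, and adjusted p = 0.229 with an estimated correlation. Each of these scores moved that way in 2 of 2 arrays. Among the lists that were higher, the LIF and STAT3 response had 10 of 23 risen and 3 fallen (12 and 3 adjusted over the list alone), with Stat3 at 3.81 (SE 0.54), Bcl6 at 3.41 (SE 0.24, floored 3.09) and Socs2 at -2.26 (SE 0.29, floored -1.11), a median of 0.60, adjusted p = 0.0186 and adjusted p = 0.423 with an estimated correlation. Interferon response genes rose in 4 of 11 cases (6 adjusted over the list alone), such as Igtp (2.17, SE 0.24, floored 1.10) and the chemokine gene Cxcl10 (2.57, SE 0.58, floored 2.22). Over the list the result was adjusted p = 0.00393, and adjusted p = 0.338 with an estimated correlation. Hypoxia and glycolysis genes were lower in 12 of 22 cases, with 1 risen (12 and 1 adjusted over the list alone). The set as a whole had adjusted p = 0.00768, and adjusted p = 0.440 with an estimated correlation.

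Skeletal muscle genes were higher after 2 uninduced days, with 4 of 9 risen (6 adjusted over the list alone) and a median of 2.23. In the test of the list this gave adjusted p = 0.000369, and adjusted p = 0.358 with an estimated correlation. The troponin C gene Tnnc1 was at 2.23 (SE 0.29). The calls of the myogenic regulators Myod1 (3.64, SE 1.11, floored 1.98) and Myog (2.80, SE 0.89) and of the desmin gene Des (0.82, SE 0.21) ended whichever of the 4 arrays was left out (highest adjusted p 0.155, 0.148 and 0.0607). The comparison gave 2525 genes, 1079 higher and 1446 lower. The count was 1087 and 994 without fresh replicates 1 and 2, and 917 and 1185 without day 2 control replicates 1 and 2. The log2 3'/5' ratio of the dap spike-in, a measure of how fully the labelled RNA reached the 5' end, averaged 1.07 in fresh, 1.37 in day 1 control and 2.00 in day 2 control arrays; with it as a covariate the day 2 count was 1672. The 5S rRNA signal, a sign of RNA quality or composition, rose as well. It was at log2 6.32 and 6.62 in fresh, 8.67 and 7.56 in day 1 control and 10.1 and 10.3 in day 2 control arrays. At least 2-fold, the balance turned to 497 genes higher and 250 lower.

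**Figure D1:**
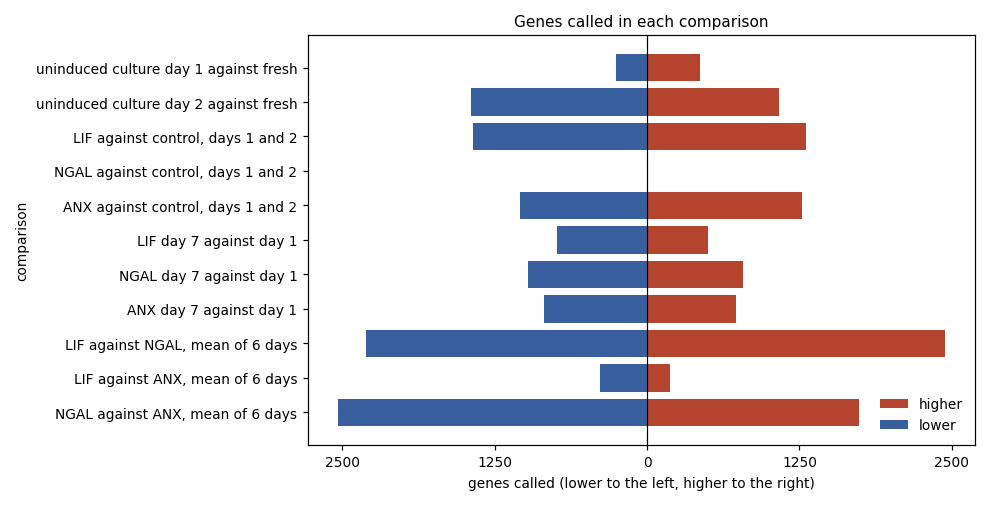
Genes called at an adjusted p under 0.05 in each of the 11 pairwise comparisons (horizontal axis: number of genes, higher to the right and lower to the left, from 11387 tested). NGAL against control has no bar because 0 genes were called, against 2732 for LIF and 2307 for ANX.

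LIF on days 1 and 2 raised cytokine response and cholesterol synthesis genes and lowered stromal, endothelial and erythroid ones (4 LIF arrays against 4 day-matched controls). Tnfaip6, a hyaluronan-binding protein of inflammation, rose by 4.02 (SE 0.59, floored 2.84) on the log2 scale, Bcl3 by 2.57 (SE 0.27), the decoy receptor gene Il1r2 by 2.48 (SE 0.28) and Socs3, a feedback inhibitor of STAT3 signalling, by 1.63 (SE 0.23). Pax8, a transcription factor of early nephrons, rose by 1.72 (SE 0.31). Wnt4, which drives the conversion of mesenchyme to epithelium, was at 1.17 (SE 0.39, adjusted p = 0.0318), but that call ended in 6 of the 8 fits that left out 1 array (highest adjusted p 0.141), and on day 2 alone its value was -0.21. Aspn, a small matrix proteoglycan, changed by -3.38 (SE 0.52, floored -1.49), the transcription factor gene Foxp2 by -3.20 (SE 0.41, floored -3.01) and Ccn2, a TGF-beta-responsive matrix protein, by -3.71 (SE 0.94, floored -2.94). In the LIF and STAT3 list 9 of 23 members rose and 0 fell by limma (9 adjusted over the list alone), with A2m at 2.32 (SE 0.31) and Irf1 at 1.25 (SE 0.13), with a median of 0.52. List-level values were adjusted p = 9.66e-05, and adjusted p = 0.227 with an estimated correlation. Cholesterol synthesis genes rose in 9 of 12 cases (9 adjusted over the list alone), such as Fdps (1.13, SE 0.15) and Dhcr7 (1.05, SE 0.18). Together these members had adjusted p = 6.18e-06, and adjusted p = 0.338 with an estimated correlation. Both scores were higher in 4 of 4 arrays.

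Renal stroma genes fell in 10 of 21 cases under LIF (15 adjusted over the list alone), among them the retinoic acid receptor gene Rarb (-1.51, SE 0.25) and the collagen gene Col1a2 (-1.68, SE 0.33), with a median of -1.08. This list had adjusted p = 3.39e-05, and adjusted p = 0.487 with an estimated correlation. Endothelial genes fell in 9 of 16 cases (9 adjusted over the list alone, Kdr -1.42, SE 0.27, Sox18 -0.74, SE 0.15). The list test gave adjusted p = 0.000487, and adjusted p = 0.345 with an estimated correlation. Erythroid genes fell in 6 of 9 cases (6 adjusted over the list alone, Hbz -1.88, SE 0.34). As a list they had adjusted p = 0.00228, and adjusted p = 0.338 with an estimated correlation. Epithelial junction and keratin genes rose in 4 of 25 cases (4 adjusted over the list alone), led by the desmosomal genes Dsc2 and Dsg2 (floored values 0.14 and 0.76). Tested together, they had adjusted p = 0.0218, and adjusted p = 0.661 with an estimated correlation. Cdh1, E-cadherin, was below the threshold in all 4 groups. Proliferation genes rose in 5 of 24 cases (5 adjusted over the list alone, Pcna 0.50, SE 0.11). For the whole list limma gave adjusted p = 0.0131, and adjusted p = 0.661 with an estimated correlation. Each of these 5 scores moved that way in 4 of 4 arrays, and the self-contained test gave no call for the epithelial and proliferation lists (adjusted p 0.115 and 0.119). The epithelial call also ended with the stricter filter (adjusted p = 0.0626). LIF changed 2732 genes against control, 1302 higher and 1430 lower; the count was 1528 without day 1 control replicate 1 and 1607 without LIF day 2 replicate 1. The mean dap ratio was 1.24 and 1.52 in LIF arrays of days 1 and 2, against 1.37 and 2.00 in the controls, and the 5S rRNA signal was at 7.02 and 7.00 on day 1 against 8.67 and 7.56, and at 7.31 and 8.70 on day 2 against 10.1 and 10.3. After quantile normalization 1496 genes were higher and 1444 lower.

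The ANX fraction on days 1 and 2 raised FGF response, cytokine response and cholesterol synthesis genes and lowered stromal and erythroid ones (4 ANX arrays against the same 4 controls). Cxcl1, a neutrophil chemokine, rose by 4.23 (SE 0.47, floored 3.56) on the log2 scale, Ptgs2, cyclooxygenase 2, by 3.95 (SE 0.46, floored 3.70), Fst by 3.43 (SE 0.38) and Upp1 by 3.27 (SE 0.32). Lcn2, which encodes NGAL itself, rose by 1.75 (SE 0.28, floored 0.94) and Pax8 by 1.69 (SE 0.31), while Socs3 was at 0.58 (SE 0.23, adjusted p = 0.0689) and Wnt4 at 0.41 (SE 0.39). Foxp2 changed by -3.50 (SE 0.41, floored -3.01) and Bnc2 by -3.39 (SE 0.51). Early nephron induction genes rose in 4 of 12 cases (4 adjusted over the list alone), including the Notch ligand gene Jag1 (1.34, SE 0.26) and Bmp2 (1.28, SE 0.23). Camera gave the list adjusted p = 0.0361, and adjusted p = 0.499 with an estimated correlation and 0.0501 with the stricter filter. FGF and MAPK response genes rose in 7 of 12 cases (7 adjusted over the list alone), among them the feedback regulators Dusp6 (1.16, SE 0.20) and Spry4 (0.85, SE 0.15), with a median of 0.61. At the list level this was adjusted p = 0.00217, and adjusted p = 0.338 with an estimated correlation. The LIF and STAT3 list rose in 8 of 23 cases (12 adjusted over the list alone, Icam1 1.69, SE 0.22, Il4r 0.69, SE 0.09). Over the list the result was adjusted p = 0.000140, and adjusted p = 0.227 with an estimated correlation. Cholesterol synthesis genes rose in 10 of 12 cases (11 adjusted over the list alone, Fdps 1.04, SE 0.15), with a median of 0.81. The set as a whole had adjusted p = 1.18e-06, and adjusted p = 0.338 with an estimated correlation.

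Renal stroma genes fell in 7 of 21 cases under ANX and 1 rose (8 and 1 adjusted over the list alone), with Rarb at -1.48 (SE 0.25) and Meis1 at -0.73 (SE 0.16). In the test of the list this gave adjusted p = 0.000428, and adjusted p = 0.553 with an estimated correlation. Erythroid genes fell in 6 of 9 cases (7 adjusted over the list alone). List-level values were adjusted p = 0.00118, and adjusted p = 0.338 with an estimated correlation. Among p53 targets 3 of 12 rose and 1 fell (6 and 1 adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a at 1.42 (SE 0.27). The p53 list had adjusted p = 0.0354, but adjusted p = 0.562 with an estimated correlation and adjusted p = 0.0752 with the 3'/5' covariate, 0.0635 with the stricter filter and 0.0643 with the mean of probe sets. Proliferation genes rose in 4 of 24 cases (4 adjusted over the list alone). Together the members had adjusted p = 0.0390, and adjusted p = 0.714 with an estimated correlation, 0.172 in the self-contained test and 0.0624 after quantile normalization. All 8 list scores moved in the called direction in 4 of 4 ANX arrays. Leaving out 1 array ended 3 of these calls. The induction call ended without day 1 control replicate 2, ANX day 1 replicate 1 or ANX day 2 replicate 2 (adjusted p 0.0657, 0.0625 and 0.0691). The p53 call ended without day 1 control replicate 1 or ANX day 1 replicate 2 (0.0840 and 0.0743), and the proliferation call without day 1 control replicate 1, ANX day 1 replicate 1 or ANX day 2 replicate 2 (0.0655, 0.0707 and 0.0647). ANX changed 2307 genes against control, 1268 higher and 1039 lower; the count was 1115 without day 1 control replicate 1, 1396 without day 2 control replicate 2, 1361 without ANX day 1 replicate 1 and 1343 without ANX day 2 replicate 1. The mean dap ratio was 0.86 and 1.70 in ANX arrays of days 1 and 2, against 1.37 and 2.00 in the controls. The 5S rRNA signal was at 7.04 and 7.02 on day 1 against 8.67 and 7.56, and at 7.11 and 7.47 on day 2 against 10.1 and 10.3. At least 2-fold, 190 genes were higher and 225 lower.

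LIF and ANX raised 859 genes in common and lowered 866, where independent lists of those sizes would share 145.0 and 130 genes, and 0 genes moved in opposite directions by limma. Their fold changes correlated at 0.883, against 0.503 in simulated unchanged groups that share the same controls. Their covariance exceeded the simulated one by 0.174. The simulated noise was independent between genes and held no shift of the control arrays in RNA or labelling. It thus cannot tell a shared response from such a shift, which separate control replicates can share too. With separate control replicates the correlations were 0.808 and 0.809. With separate control replicates for each inducer, 235 genes rose and 275 fell in both for 1 allocation (32.0 and 27.8 for independent lists), and 270 and 347 for the other (33.8 and 31.6).

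For NGAL no single gene was called against control on days 1 and 2: limma gave 0 of 11387 genes, with 799 at an unadjusted p under 0.05 and a smallest adjusted p of 0.101. Lcn2 was below the threshold in NGAL and control cultures. Pax8 was at 0.52 (SE 0.31), Wnt4 at -0.04 (SE 0.39) and Socs3 at 0.04 (SE 0.23), none called. Lists gave small shifts: cholesterol synthesis was higher (median 0.39, 3 of 4 arrays, adjusted p = 5.25e-06, adjusted p = 0.338 with an estimated correlation), as were FGF and MAPK response (median 0.22, 4 of 4 arrays, adjusted p = 0.00422, adjusted p = 0.338 with an estimated correlation) and nephron progenitor genes (median 0.20, 4 of 4 arrays, adjusted p = 0.0225, adjusted p = 0.580 with an estimated correlation). Renal stroma was lower (median -0.29, 4 of 4 arrays, adjusted p = 0.0275, adjusted p = 0.661 with an estimated correlation). Adjusted over the list alone, 2 cholesterol and 2 FGF genes rose, 1 stroma gene fell and 0 progenitor genes changed. The self-contained test called 0 lists here. Without day 1 control replicate 1 the progenitor call ended (adjusted p = 0.262, score difference 0.12 against 0.26 with all arrays), as it did without day 2 control replicate 2 (0.0526) or NGAL day 2 replicate 2 (0.167), and without day 1 control replicate 2 the difference was 0.40. The stroma call ended without day 1 control replicate 2 (0.117) or NGAL day 1 replicate 1 (0.0529). Mean dap ratios were 1.27 and 1.81 in NGAL arrays of days 1 and 2, against 1.37 and 2.00 in the controls. The 5S rRNA signal was lower too, at 7.10 and 6.85 on day 1 against 8.67 and 7.56, and at 9.63 and 9.36 on day 2 against 10.1 and 10.3. The gene count was 15 without day 1 control replicate 2, 23 with array weights, 17 from only the arrays compared, 1 with no filter and 0 with the 3'/5' covariate. NGAL fold changes correlated with those of LIF at 0.759 and of ANX at 0.823, against 0.502 and 0.501 in simulated unchanged groups with the same controls. With separate control replicates these were 0.564 and 0.629 for LIF, and 0.678 and 0.623 for ANX. The simulated noise held no shift of the control arrays in RNA or labelling. Neither comparison can therefore tell a shared response from such a shift.

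**Figure D2:**
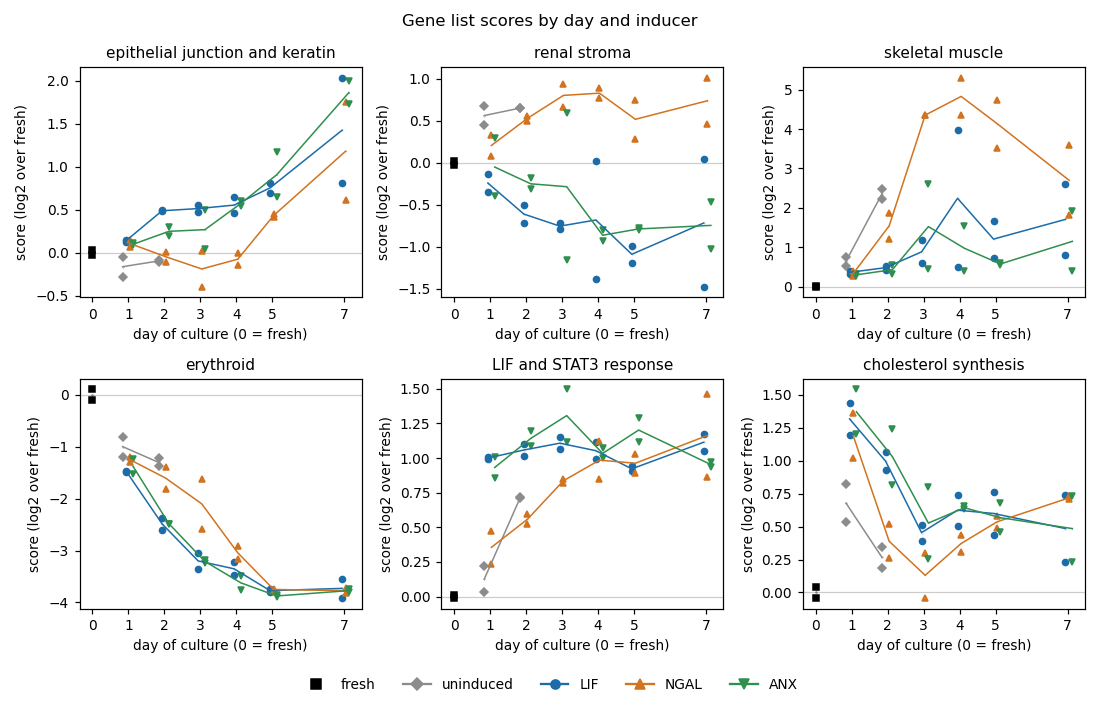
Scores of 6 gene lists (vertical axis: mean log2 level of the measured members over fresh tissue) against day of culture; points are arrays and lines join the means of 2 arrays per group. Muscle scores of NGAL arrays on days 3 to 7 run from 1.81 to 5.30, and the erythroid scores fall in all inducers.

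From day 1 to day 7 epithelial genes rose and erythroid genes fell with each inducer (2 arrays against 2). There was no uninduced control after day 2, so time and inducer are not separated. Epcam, an epithelial adhesion molecule, rose by 3.52, 3.41 and 4.61 on the log2 scale (SE 0.51 each, floored 3.20, 3.17 and 4.17) in LIF, NGAL and ANX cultures. Fxyd2, a modulator of the sodium pump in distal nephron, rose by 3.80, 4.07 and 3.05 (SE 0.60 each, floored 3.55 and 3.37 in LIF and NGAL), and Pou3f3, a transcription factor of loop and distal tubule, by 3.98, 4.29 and 5.20 (SE 0.82 each, floored 2.17, 2.77 and 3.48). Cdh1 was at 2.76, 3.15 and 4.56 (SE 0.75 each, floored 0.94, 1.66 and 2.78). In LIF cultures the calls of Cdh1 and Pou3f3 ended without day 7 replicate 2 (adjusted p 0.455 and 0.0851), and that of Cdh1 in 3 of the 4 fits without 1 array; in NGAL cultures the call of Cdh1 ended without day 7 replicate 2 (adjusted p 0.0598). Hbe1, an embryonic globin, stood at a mean log2 level of 13.67 in fresh tissue and fell by at least 6.37, 6.75 and 6.52 from day 1 to levels below the threshold on day 7.

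By list, epithelial junction and keratin genes rose in 14 of 25 cases in LIF cultures, 12 in NGAL and 20 in ANX (19, 14 and 22 adjusted over the list alone, with 1 fallen in NGAL), with medians of 1.41, 0.98 and 1.51 and adjusted p = 2.97e-12, 7.14e-08 and 4.33e-17; with an estimated correlation these were adjusted p = 0.287, 0.345 and 0.227. Loop of Henle and distal tubule genes rose in 4, 2 and 5 of 9 cases (6, 2 and 7 adjusted over the list alone). Only 9 of its 23 members were measured, 4 of them above the threshold in fresh tissue. Members below the threshold in every group were not counted, among them Umod, Slc12a3, Calb1 and Egf. This list had adjusted p = 0.000103, 0.0225 and 8.07e-05, and adjusted p = 0.227, 0.408 and 0.227 with an estimated correlation, and the call in NGAL cultures ended without filter (adjusted p = 0.0512). Early nephron induction genes rose in 4, 7 and 6 of 12 cases, with 1 fallen in each, Lef1, whose call in LIF cultures ended in 2 of the 4 fits without 1 array (5, 7 and 6 risen adjusted over the list alone). The list test gave adjusted p = 0.00235, 0.000103 and 0.00475, and adjusted p = 0.338, 0.227 and 0.338 with an estimated correlation. Jag1 rose by 2.96 in NGAL and by 2.49 in ANX cultures (SE 0.37 each), and Bmp2 by 2.41 in LIF and by 1.59 in ANX cultures (SE 0.33 each). Proximal tubule genes were called higher in LIF (0 of 19 members risen by limma, also adjusted over the list alone) and ANX cultures (4 of 19, and 4 adjusted over the list alone). As a list they had adjusted p = 0.0332 and 0.0288, and adjusted p = 0.553 each with an estimated correlation. Only 1 of 2 day 7 arrays was higher in both, and these calls ended in arrays with a low 3'/5' ratio (adjusted p 0.122 and 0.791), with the 3'/5' covariate (0.0517 and 0.0606), with the stricter filter (0.219 and 0.238), after quantile normalization (0.141 and 0.0799) and with the self-contained test (0.140 and 0.0791).

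The size of these day 7 rises depended on single arrays. Day 7 replicate 2 had a high dap ratio in LIF, NGAL and ANX cultures (2.30, 1.97 and 2.20). In day 7 replicate 1 the ratio was 1.19, 1.32 and 1.17. The fit of low 3'/5' arrays left out day 7 replicate 2 too, so it and the fit without that array are not separate evidence. Without LIF day 7 replicate 2 the difference in mean score went from 1.28 to 0.67 for epithelial genes, from 1.52 to 0.86 for loop genes and from 0.95 to 0.60 for induction genes, whose call ended (adjusted p = 0.0628). In NGAL cultures the epithelial difference of 1.07 was 0.50 without day 7 replicate 2 and 1.64 without day 7 replicate 1, and the loop call ended without day 1 replicate 2 or day 7 replicate 2 (adjusted p 0.0932 and 0.0583). The epithelial calls stayed under 0.05 in each of these fits. Proximal tubule calls ended without day 1 replicate 2 (0.177 in LIF, 0.142 in ANX) or day 7 replicate 2 (0.241 and 0.861). Without that day 7 array their differences went from 0.34 to -0.017 in LIF and from 0.45 to -0.06 in ANX, and without day 7 replicate 1 they were 0.70 and 0.95.

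Erythroid genes fell in 4, 5 and 4 of 9 cases in LIF, NGAL and ANX cultures (5, 6 and 7 adjusted over the list alone). Tested together, they had adjusted p = 6.82e-06, 3.23e-07 and 6.91e-07, and adjusted p = 0.227 each with an estimated correlation. Endothelial genes fell in 6, 8 and 9 of 16 (7, 9 and 9 adjusted over the list alone), with Sox17 lower by at least 0.99, 1.92 and 2.38, as its day 7 levels were below the threshold. For the whole list limma gave adjusted p = 0.00228, 0.000477 and 1.05e-06, and adjusted p = 0.423, 0.345 and 0.227 with an estimated correlation. In arrays with a low 3'/5' ratio the endothelial call in NGAL cultures ended (adjusted p = 0.193). Proliferation genes fell in 18, 19 and 12 of 24 (21, 22 and 16 adjusted over the list alone), with Birc5 at -0.82, -1.03 and -0.89 (SE 0.16 each). Camera gave the list adjusted p = 5.74e-13, 3.91e-11 and 1.23e-06, and adjusted p = 0.322, 0.338 and 0.471 with an estimated correlation. Cholesterol synthesis genes fell in 7, 3 and 7 of 12 (8, 6 and 10 adjusted over the list alone). At the list level this was adjusted p = 1.20e-05, 0.0218 and 9.58e-06, and adjusted p = 0.338, 0.607 and 0.338 with an estimated correlation; Insig1 was at -1.34 in LIF and -1.31 in ANX cultures (SE 0.26 each). Glucocorticoid targets rose in 4, 5 and 3 of 11 (5, 6 and 5 adjusted over the list alone, with 1 fallen in LIF), with the metallothionein gene Mt2A at 2.83, 2.12 and 2.50 (SE 0.43 each). Over the list the result was adjusted p = 0.00319, 4.44e-06 and 0.0228, and adjusted p = 0.338, 0.227 and 0.440 with an estimated correlation. Except for the proximal tubule, every list score called here moved in the called direction in 2 of 2 day 7 arrays. In NGAL cultures the endothelial call ended without day 7 replicate 2 (adjusted p = 0.0690) and the cholesterol call without day 1 replicate 2 (0.105, score difference -0.30 against -0.47) or day 7 replicate 2 (0.110). The proliferation difference there was -0.48 without day 7 replicate 1, against -0.73.

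Further lists were called in 1 or 2 of the inducers, without a test of the difference between inducers. In NGAL cultures nephron progenitor genes fell in 5 of 15 cases (7 fallen and 1 risen adjusted over the list alone, Meox1 -2.00, SE 0.47). The set as a whole had adjusted p = 0.0158, and adjusted p = 0.555 with an estimated correlation. The LIF and STAT3 list rose in 7 of 23 (7 adjusted over the list alone, Ccl2 4.24, SE 0.55, floored 3.49, Bcl6 2.08, SE 0.24). In the test of the list this gave adjusted p = 2.65e-05, and adjusted p = 0.227 with an estimated correlation. Muscle genes rose there in 3 of 9 (4 adjusted over the list alone). List-level values were adjusted p = 0.00162, and adjusted p = 0.440 with an estimated correlation. The single calls of Acta1 (5.32, SE 1.68, floored 4.34), Myl1 (5.09, SE 1.55, floored 3.62) and Myh3 (3.73, SE 1.11, floored 3.17) ended in 4, 4 and 3 of the 4 fits without 1 array (highest adjusted p 0.155, 0.171 and 0.189). TGF-beta targets had 1 of 13 risen and 2 fallen in NGAL cultures (6 and 2 adjusted over the list alone) with a median of 0.54. Its members together had adjusted p = 0.0372, and adjusted p = 0.555 with an estimated correlation, 0.133 in the self-contained test and 0.358 in arrays with a low 3'/5' ratio. Hypoxia and glycolysis genes rose in 3 of 22 in NGAL (3 adjusted over the list alone) and 9 of 22 in ANX cultures (13 adjusted over the list alone, Egln3 2.98, SE 0.43, floored 2.89, Bnip3 1.34, SE 0.23). This list had adjusted p = 0.0441 and 7.59e-07, and adjusted p = 0.555 and 0.227 with an estimated correlation. The NGAL call of hypoxia genes also ended in the self-contained test (adjusted p = 0.140), with the stricter filter (0.0683), with the mean of probe sets (0.0632) and in arrays with a low 3'/5' ratio (0.0584). In ANX cultures Wnt/beta-catenin targets rose in 5 of 11 with 1 fallen (5 and 1 adjusted over the list alone, Apcdd1 1.16, SE 0.23). The list test gave adjusted p = 0.0227, and adjusted p = 0.338 with an estimated correlation. Renal stroma genes fell there in 5 of 21 (7 fallen and 1 risen adjusted over the list alone, Tbx18 -2.07, SE 0.32, floored -0.90). As a list they had adjusted p = 0.0174, and adjusted p = 0.637 with an estimated correlation and 0.133 in the self-contained test. In LIF cultures p53 targets rose in 1 of 12 (3 adjusted over the list alone). Tested together, they had adjusted p = 0.0303, and adjusted p = 0.555 with an estimated correlation, 0.138 in the self-contained test and 0.156 with the mean of probe sets.

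Most calls of these further lists ended without 1 array. In NGAL cultures the progenitor call ended without day 7 replicate 1 (adjusted p = 0.167, score difference -0.33 against -0.77, and -1.21 without day 7 replicate 2) and the muscle call without day 7 replicate 2 (0.0599, 1.48 against 2.37). TGF-beta targets lost their call without day 1 replicate 1 (0.172, 0.37 against 0.71) or day 7 replicate 2 (0.170), and hypoxia genes without day 1 replicate 1 (0.131, 0.18 against 0.28) or day 7 replicate 1 (0.244). The LIF and STAT3 difference there was 0.50 without day 7 replicate 1, against 0.81. In ANX cultures the stroma call ended without day 1 replicate 2 (0.0885, -0.35 against -0.70) or day 7 replicate 1 (0.142, -0.41), and the Wnt call without day 1 replicate 2 (0.0539). The p53 call in LIF cultures ended without day 1 replicate 1 (0.0533) or day 7 replicate 1 (0.183).

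The day 7 comparisons called 1241 genes in LIF (500 higher, 741 lower), 1767 in NGAL (788 and 979) and 1575 in ANX cultures (729 and 846). After quantile normalization the balance turned in LIF (674 higher, 628 lower) and in ANX cultures (903 and 755), and at least 2-fold in all 3 (210 and 148, 439 and 172, 305 and 221). Fits of only the arrays compared called 30, 144 and 586 genes. The LIF count was 473 and 345 without day 1 replicates 1 and 2 and 730 without day 7 replicate 1. The NGAL count was 563 without day 1 replicate 2 and 529 without day 7 replicate 1. The ANX count was 732 and 720 without day 1 replicates 1 and 2, and 911 and 846 without day 7 replicates 1 and 2. Mean dap ratios on days 1 and 7 were 1.24 and 1.75 in LIF, 1.27 and 1.65 in NGAL and 0.86 and 1.69 in ANX arrays; in arrays with a low ratio the counts were 817 for LIF, 1601 for NGAL and 761 for ANX.

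**Figure D3:**
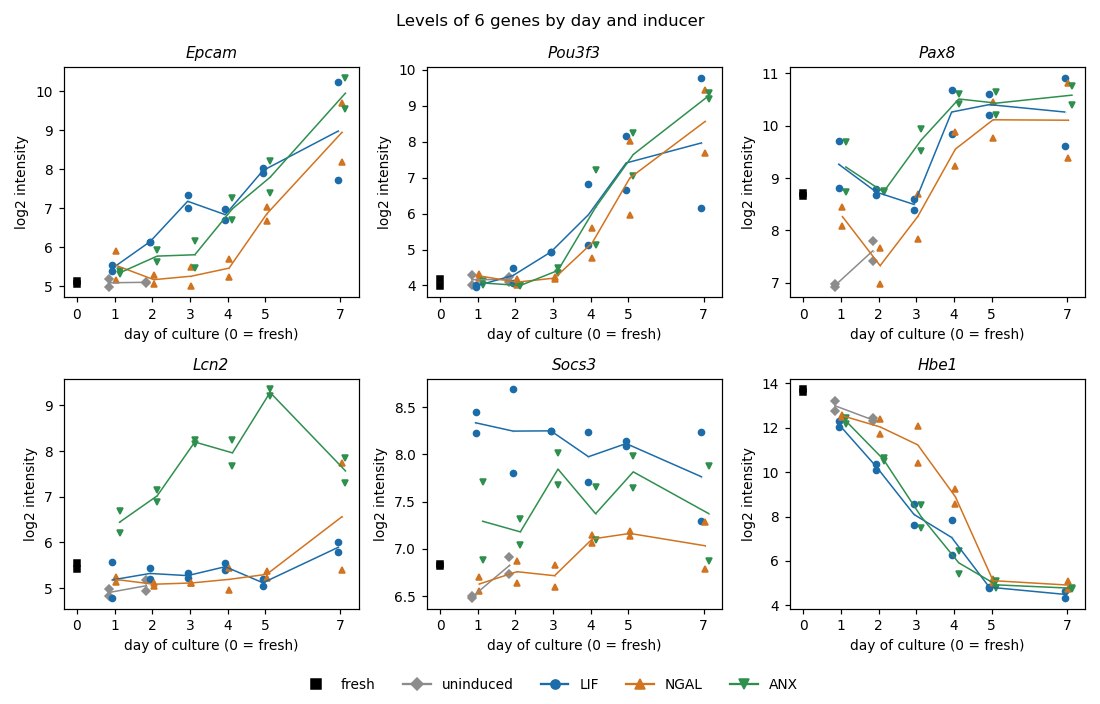
Log2 intensity of 6 genes against day of culture; points are arrays and lines join the means of 2 arrays per group. Hbe1 falls from 13.67 in fresh tissue to below the threshold of 5.79 on day 7 with each inducer, and Lcn2 reaches 9.28 on day 5 in ANX cultures, against 5.12 in LIF and 5.30 in NGAL cultures.

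Over the 6 days (12 arrays per inducer), stroma, muscle, macrophage and TGF-beta target genes were higher in NGAL cultures than in LIF or ANX cultures. Renal stroma genes were lower in LIF than in NGAL in 20 of 21 cases (20 adjusted over the list alone, median -1.32, 12 of 12 arrays, adjusted p = 9.24e-10, adjusted p = 0.338 with an estimated correlation). They were higher in NGAL than in ANX in 18 of 21, with 1 lower (19 and 1 adjusted over the list alone, mean 1.10, 12 of 12 arrays, adjusted p = 2.28e-10, adjusted p = 0.322 with an estimated correlation). Col1a2 differed by -1.94 (SE 0.19) for LIF against NGAL and by 1.59 (SE 0.19) for NGAL against ANX, and Ccn2 by -4.37 and 3.98 (SE 0.54 each, floored -4.03 and 3.87). Muscle genes were lower in LIF than in NGAL in 7 of 9 cases (8 adjusted over the list alone, median -2.22, 11 of 12 arrays, adjusted p = 0.000149, adjusted p = 0.345 with an estimated correlation). Against ANX they were higher in NGAL in 9 of 9 (9 adjusted over the list alone, median 2.46, 11 of 12 arrays, adjusted p = 1.45e-07, adjusted p = 0.227 with an estimated correlation). The skeletal actin gene Acta1 reached a mean log2 level of 12.27 in NGAL cultures on day 4, from 4.27 in fresh tissue, and Myh3, embryonic myosin heavy chain, reached 11.33. TGF-beta targets, of which Col1a1, Acta2 and Tagln are also in the stroma list, were lower in LIF than in NGAL in 10 of 13 cases with 1 higher (10 and 1 adjusted over the list alone, adjusted p = 0.000158, adjusted p = 0.338 with an estimated correlation). NGAL was above ANX for 7 of them and below for 1 (7 and 1 adjusted over the list alone, adjusted p = 0.00314, adjusted p = 0.408 with an estimated correlation). Macrophage and leukocyte genes were lower in LIF than in NGAL in 7 of 12 (7 adjusted over the list alone, Mrc1 -1.42, SE 0.23, floored -1.09, adjusted p = 0.0225, adjusted p = 0.586 with an estimated correlation). In NGAL against ANX 7 of 12 were higher (7 adjusted over the list alone, Lyz2 1.07, SE 0.18, adjusted p = 0.00390, adjusted p = 0.551 with an estimated correlation).

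Mean dap ratios were 1.44, 1.36 and 1.25 in LIF, NGAL and ANX arrays, and the 5S rRNA signal averaged 8.01, 7.86 and 7.08. The 3'/5' ratio of labelled RNA and this sign of RNA quality or composition thus differed between inducers too.

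Nephron progenitor, epithelial and proliferation genes went the other way. For LIF against NGAL, Draxin was higher by 3.06 (SE 0.28, floored 2.85) and Eya2 by 2.34 (SE 0.24). Nephron progenitor genes were higher in 8 of 15 cases and lower in 1 (8 and 2 adjusted over the list alone, Hoxa11 0.49, SE 0.09, adjusted p = 0.0440, adjusted p = 0.628 with an estimated correlation). That progenitor call ended with the replicate block (adjusted p = 0.0555), with the stricter filter (0.0608) and after quantile normalization (0.0648). Epithelial genes were higher in 10 of 25 (10 adjusted over the list alone, adjusted p = 0.00642, adjusted p = 0.630 with an estimated correlation). For NGAL against ANX, progenitor genes were lower in 10 of 15 (11 lower and 1 higher adjusted over the list alone, Wt1 -0.67, SE 0.16, adjusted p = 0.0163, adjusted p = 0.555 with an estimated correlation). Epithelial genes were lower in 10 of 25 (11 adjusted over the list alone, Dsg2 -1.14, SE 0.18, floored -0.64, adjusted p = 0.00390, adjusted p = 0.624 with an estimated correlation). Proliferation genes were higher in LIF than in NGAL in 11 of 24 (11 adjusted over the list alone, Aurka 0.46, SE 0.07, adjusted p = 0.0126, adjusted p = 0.661 with an estimated correlation, and 0.0697 in arrays with a low 3'/5' ratio). NGAL was below ANX for 15 of 24 (16 adjusted over the list alone, Plk1 -0.33, SE 0.07, adjusted p = 0.00110, adjusted p = 0.614 with an estimated correlation). Erythroid genes were higher in NGAL than in ANX in 4 of 9 with 1 lower (4 and 1 adjusted over the list alone, Hbe1 1.37, SE 0.19, floored 1.32, adjusted p = 0.010, adjusted p = 0.415 with an estimated correlation). LIF was below NGAL for podocyte genes (6 of 13 lower and 2 higher, 7 and 2 adjusted over the list alone, Nes -1.17, SE 0.14, adjusted p = 0.0347, adjusted p = 0.345 with an estimated correlation and 0.0659 without filter). It was also below NGAL for endothelial genes (7 of 16 lower and 1 higher, 7 and 1 adjusted over the list alone, adjusted p = 0.0169, adjusted p = 0.553 with an estimated correlation). The same held for glucocorticoid targets (8 of 11 lower and 1 higher, 8 and 1 adjusted over the list alone, adjusted p = 0.0264, adjusted p = 0.451 with an estimated correlation), although Mt2A was higher by 1.66 (SE 0.17). Each of these scores moved in the called direction in 10 or 11 of 12 arrays. For LIF against NGAL the epithelial, macrophage and proliferation calls ended without LIF day 7 replicate 2 (adjusted p 0.0724, 0.0690 and 0.0735). The progenitor call ended in 9 fits, without replicate 1 of LIF days 1, 2, 4 and 7 and of NGAL days 2, 3, 4 and 7, and without NGAL day 5 replicate 2 (highest adjusted p 0.0671). In all, 4750 genes differed between LIF and NGAL (2442 higher, 2308 lower) and 4272 between NGAL and ANX (1741 higher, 2531 lower). At least 2-fold the balance turned, with 100 higher and 341 lower for LIF against NGAL and 278 higher and 81 lower for NGAL against ANX.

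Among called genes with the same sign on every day, Cxcl1 and the lipoprotein lipase gene Lpl were furthest below ANX in LIF cultures. Cxcl1 was at -3.88 (SE 0.27, floored -3.66) in LIF against ANX, Lpl at -2.48 (SE 0.33, floored -2.41), Lcn2 at -2.37 (SE 0.16, floored -1.94), Ccl2, a monocyte chemokine, at -2.19 (SE 0.22) and Ptgs2 at -2.01 (SE 0.27), while Draxin (2.04, SE 0.28, floored 2.02), Eya2 (1.69, SE 0.24) and Socs3 (0.63, SE 0.13) were higher in LIF. Lcn2 was also lower in NGAL than in ANX (-2.34, SE 0.16, floored -1.83). Of 13 iron handling genes 1 was lower in LIF, Lcn2 (2 adjusted over the list alone, 12 of 12 arrays, adjusted p = 0.0218, adjusted p = 0.227 with an estimated correlation). Hypoxia and glycolysis genes were lower in 5 of 22 (7 adjusted over the list alone, Slc2a1 -0.52, SE 0.08, 11 of 12 arrays, adjusted p = 0.000311, adjusted p = 0.338 with an estimated correlation). Of 12 p53 targets 4 were lower (5 adjusted over the list alone, Cdkn1a -0.73, SE 0.16, 11 of 12 arrays, adjusted p = 0.000765, adjusted p = 0.350 with an estimated correlation). TGF-beta targets were lower in 3 of 13 (4 adjusted over the list alone, Tgfb1 -0.81, SE 0.14, 10 of 12 arrays, adjusted p = 0.0203, adjusted p = 0.552 with an estimated correlation). Podocyte genes were lower in 2 of 13 (4 adjusted over the list alone, Vegfa -0.56, SE 0.12, 12 of 12 arrays). Vegfa is in the hypoxia and glycolysis list too. By camera the podocyte list had adjusted p = 0.0336, and adjusted p = 0.345 with an estimated correlation. Its adjusted p was 0.0671 without filter and 0.0548 with the mean of probe sets. Neuron and Schwann cell genes were higher in 2 of 9 (3 adjusted over the list alone, Tubb3 0.60, SE 0.14, 10 of 12 arrays, adjusted p = 0.0191, adjusted p = 0.338 with an estimated correlation). That call ended after quantile normalization (adjusted p = 0.0620), in arrays with a low 3'/5' ratio (0.156) and without filter (0.0507). Muscle genes had 0 of 9 members called by limma (0 adjusted over the list alone, median 0.27, 8 of 12 arrays, adjusted p = 0.0275, adjusted p = 0.577 with an estimated correlation), and that call ended with the 3'/5' covariate (adjusted p = 0.0769), in the self-contained test (0.258), after quantile normalization (0.0707) and in arrays with a low 3'/5' ratio (0.240). The muscle call also ended without LIF day 4 replicate 2, LIF day 7 replicate 2, ANX day 3 replicate 1 or ANX day 7 replicate 1 (0.281, 0.101, 0.115 and 0.0550), with score differences of 0.03, 0.17, 0.14 and 0.19 against 0.32, and this was 0.61 and 0.50 without LIF day 4 replicate 1 and ANX day 3 replicate 2. The neuron call ended without LIF day 4 replicate 2 (0.0570). The podocyte call ended without LIF day 4 replicate 1, LIF day 7 replicate 1, ANX day 3 replicate 1 or ANX day 7 replicate 2 (0.0638, 0.104, 0.0548 and 0.0671). The 5S rRNA signal ran from 7.00 to 9.21 in LIF and from 6.30 to 7.62 in ANX arrays. The comparison gave 570 genes, 186 higher and 384 lower.

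The count for LIF against ANX depended on single arrays. It was 332, 306, 359, 310, 374 and 359 without LIF day 1 replicate 2, day 2 replicate 2, day 3 replicate 1, day 4 replicate 1, day 5 replicate 1 and day 7 replicate 1, and 951 without LIF day 7 replicate 2. Among ANX arrays it was 351, 291, 378, 370 and 370 without day 1 replicate 2, day 2 replicate 1, day 3 replicate 2, day 4 replicate 1 and day 7 replicate 1, and 976 without day 3 replicate 1.

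The time courses differed between inducers in 4 genes by a moderated F-test (660 at an unadjusted p under 0.05): Sox17 and C3 (adjusted p = 0.0223 each), Cds1 (0.0319) and Ttn (0.0440), singled out after their values were seen. Sox17, an endothelial transcription factor, was at 7.36 on day 4 in LIF, 6.43 in ANX and 4.78 (below the threshold) in NGAL cultures. In LIF cultures it was at 5.61 on day 3, also below the threshold. The complement gene C3 reached 6.36 on day 5 in ANX cultures. All its other means with an inducer lay below the threshold, so its course cannot be read beyond that point. The titin gene Ttn reached 8.01 on day 4 in NGAL cultures, against 5.97 in LIF and 5.41 (below the threshold) in ANX. The number of genes ran from 0 without LIF day 2 replicate 1 to 72 without NGAL day 7 replicate 2, over the 36 fits that left out 1 array, with 0 under the stricter filter or with only the arrays compared. For the day 2 effect of each inducer less its day 1 effect, limma called 0 genes (456, 290 and 374 at an unadjusted p under 0.05 for LIF, NGAL and ANX).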

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

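Of the tests below, the permutation of muscle scores, the 3'/5' covariate, the comparison of scatter and the counts from single arrays were chosen only after results were seen; groups held 2 arrays, too few to test for a single array far from the rest. The inducers' time courses differed in 4 genes by the F-test: Sox17 and C3 (adjusted p = 0.0223 each), Cds1 (0.0319) and Ttn (0.0440). The change from day 1 to day 7 differed between LIF and NGAL in 1 gene, Rasd1 (-3.35, SE 0.56, adjusted p = 0.0347), and between NGAL and ANX in 6 genes (adjusted p = 0.0480 each): Papss2 (3.43, SE 0.66, floored 3.42), Rasd1 (2.92, SE 0.56), Trim47 (1.94, SE 0.37), Fam180a (1.70, SE 0.31), Sertad1 (1.08, SE 0.19) and Ush1c (-2.29, SE 0.44). Between LIF and ANX limma called 0 genes in that test, with 217 at an unadjusted p under 0.05. On days 1 and 2 the effects against control differed between LIF and NGAL in 589 genes, between LIF and ANX in 71 and between NGAL and ANX in 241. Among the 5057 probe sets past the threshold that lack a single gene and were left out of the comparisons, 54 were called at least 2-fold higher than control and 155 lower with LIF, and 43 higher and 117 lower with ANX.

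A first pattern is that 0 genes were called for NGAL against control on days 1 and 2 by limma (799 at an unadjusted p under 0.05), against 2732 for LIF. A 3'/5' difference that hides calls is argued against by the covariate fit, which also called 0 genes. The ratio of within-group SD was 1.04, NGAL over LIF. That ratio decides nothing about larger scatter as a cause. The fit pooled the spread over all arrays, so the mean squared SE was 0.0341 for both inducers whatever their own scatter. The ratio of fold change variances beyond error, NGAL over LIF, was 0.0577, so a smaller early response to NGAL may account for the count. The ratio of variances comes from the same fold changes and standard errors as the count, so it restates the pattern and is no independent support. The count was 15 without day 1 control replicate 2. On day 2 the 5S rRNA signal was 10.1 and 10.3 in control and 9.63 and 9.36 in NGAL arrays. It was further from control in LIF (7.31 and 8.70) and ANX arrays (7.11 and 7.47). On day 1 NGAL arrays (7.10 and 6.85) were as low as LIF (7.02 and 7.00) and ANX arrays (7.04 and 7.02). No fit took this signal as a covariate, so its part in the LIF and ANX counts is open. Whether a different dose of NGAL would act otherwise was not tested.

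A further pattern is the muscle genes, higher in NGAL cultures (mean score 2.98 over 12 arrays) than in LIF (1.15) or ANX cultures (0.83). With the 3'/5' covariate the list had adjusted p = 2.13e-07 for NGAL against ANX by camera at the preset correlation of 0.01. Without the covariate it was 1.45e-07, and 0.227 with an estimated correlation. The preset values are likely too small, as muscle genes correlated at a mean of 0.412 within groups. The covariate left the preset result nearly unchanged, which argues against the 3'/5' difference as the whole cause. Chance allocation of explants with muscle precursors is argued against by a permutation test that moved arrays between inducers within days. It gave a one-sided permutation p = 2e-05 from 100000 resamples, and permutation p = 8e-05 for days 3 to 7, a window chosen after the scores were seen. The muscle list and NGAL were picked because they were high in these same data, and these p-values make no allowance for that. The test also takes arrays as independent, and which explants shared a dissection is not given in the sources used here. Muscle genes also varied together within groups (mean correlation 0.412, above all of 10000 random lists but below the level set in advance for this explanation). Without inducer the score was 2.36 on day 2, against 1.54 in NGAL, 0.48 in LIF and 0.43 in ANX cultures. On days 1 and 2 it was below control in 4 of 4 arrays with each inducer (differences -0.56, -1.08 and -1.13 for NGAL, LIF and ANX, not called by camera), and later days had no uninduced control. Uninduced cultures and single LIF and ANX arrays had muscle genes, so muscle lineage cells present in some explants may be a source that NGAL retains or LIF and ANX suppress; these cannot be told apart without counts of cells. Of the 9 measured muscle genes 4 were above background in fresh tissue, and 0 are in another list.

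The last pattern is that uninduced culture gave 3.66 times as many genes on day 2 as on day 1, where the mean dap ratio was 2.00 and 1.37. With the 3'/5' covariate the ratio of counts was 1.94, so the 3'/5' difference could account for part of it. Fresh arrays (dap ratio 1.06 and 1.08) and day 2 control arrays (1.97 and 2.04) did not overlap. The covariate fit thus rests on a slope from other groups and cannot show that the rest of the ratio of counts has another cause. Without day 1 control replicate 2 the ratio was 5.02, but this set 1 day 1 array against 2 of day 2 and decides nothing. With 1 control array at a time, day 1 replicates 1 and 2 gave 504 and 184 genes and day 2 replicates 1 and 2 gave 1185 and 917. Replicate 2 of day 1 thus lay nearer fresh tissue. Its dap ratio was 0.77, below that of the fresh arrays, while replicate 1 was at 1.97, as high as the day 2 controls. That array and the 3'/5' difference are therefore not separate explanations. Either way, replicate 2 of day 1 could account for part of the lower day 1 count. Without it the lowest ratio was 1.82, against a ratio of 1.29 between the day 2 arrays, so that array and a further day of culture cannot be told apart with 2 arrays per group. The biological difference, a further day of culture, stays open.

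Other splits of the same arrays, with day as a term, tested whether chance could give as many genes. No other split gave as many genes for LIF against control (3024 genes, highest other 353) or ANX against control (2850 and 998), of 34 splits each. The same held for LIF against NGAL (4674 and 2177) and NGAL against ANX (4029 and 3037), of 100 splits each. The real split counts as 1 of them, so 1 of 34 is the lowest share that test can give. Splits also take arrays as independent, and shared dissections are not given in the sources used here. Chance is thus argued against but not excluded. For NGAL against control the real split gave 3 genes and the highest other 2 (1 of 34), a gap of 1 gene on which nothing rests, and the fit to all arrays called 0. For LIF against ANX 2 of 100 splits gave as many, the real one with 484 genes and another with 1108; this points to a structure of these arrays. Whether it goes with the 3'/5' ratio is open: that split ranked 2 of the 100 by its difference in dap ratio (0.448), and the highest other splits of each inducer against control ranked 1 of 34, but those of LIF against NGAL and NGAL against ANX ranked 72 and 77 of 100. With the covariate the real comparison called 659 genes.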

How the results depend on the processing

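The 3'/5' covariate, the fit of low 3'/5' arrays and leaving out arrays for gene lists were tests chosen only after the data were seen; the other alternatives were planned. Each group held 2 arrays, so leaving out 1 also leaves 1. Over those fits the number of genes ran from 180 to 504 for uninduced day 1 and 917 to 1185 for day 2; 1528 to 2841, 0 to 15 and 1115 to 2578 for LIF, NGAL and ANX against control; 345 to 1165, 529 to 2150 and 720 to 911 for day 7 against day 1 in LIF, NGAL and ANX; 4187 to 5068 for LIF against NGAL, 291 to 976 for LIF against ANX, 3468 to 4608 for NGAL against ANX; and 0 to 72 for the F-test. Of 424 calls of named genes 107 were lost in at least 1 such fit, 12 with the 3'/5' covariate, 8 after quantile normalization and 0 with the replicate block.

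The 2-fold minimum can only remove calls; where other settings moved a count by more than 1.5 times, the cause was not tested. At least 2-fold: uninduced day 1 239 and day 2 747; LIF 494 and ANX 415 against control; day 7 against day 1 358 (LIF), 611 (NGAL) and 526 (ANX); 441 for LIF against NGAL, 27 for LIF against ANX and 359 for NGAL against ANX. Day 1 only: LIF 949, NGAL 2, ANX 740 against control; day 2 only: LIF 927, ANX 604. Days 1 and 2 only gave 589, 71 and 241 genes for LIF against NGAL, LIF against ANX and NGAL against ANX, and days 5 and 7 only 1974, 15 and 1918. Only the arrays compared: uninduced day 2 5859, NGAL against control 17, day 7 against day 1 30 (LIF), 144 (NGAL) and 586 (ANX), LIF against ANX 314, F-test 0. Array weights: uninduced day 1 1890 and day 2 6164, NGAL 23 and ANX 3644 against control, day 7 against day 1 328 (LIF) and 835 (NGAL), F-test 8. Low 3'/5' arrays: uninduced day 1 89, day 7 against day 1 817 (LIF) and 761 (ANX); no day 2 control array was low, so uninduced day 2 and the inducers against control could not be fitted. The 3'/5' covariate gave 1672 for uninduced day 2. All probe sets gave 6409 for NGAL against ANX and 2 for the F-test; the mean of a gene's probe sets gave 1 for NGAL against control and 2 for the F-test; no filter gave 1 for NGAL against control; the stricter filter gave 0 for the F-test and the replicate block 7. Whether replicate numbers mark shared batches is open. Over 210 pairs of groups the median correlation of their replicate differences was 0.0652 (-0.646 to 0.742), with 88 above 0.1 and 53 below -0.1. These correlations went with the product of the paired groups' replicate differences in dap ratio (Spearman 0.657, permutation p = 0.000999 from 1000 permutations). Replicate 2 had the higher dap ratio with each inducer on days 2 and 7. Genes shared by LIF and ANX were 510 and 617 with split controls (main 1725), and 2 for LIF and NGAL and for NGAL and ANX in 1 allocation each. Quantile normalization took the higher share of calls from 62.8% to 51.7% for uninduced day 1 from 40.3% to 51.8% for LIF and from 46.3% to 54.5% for ANX day 7 against day 1.

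With an estimated correlation 0 lists were called in each of the 11 comparisons. The preset correlation of 0.01 can be too low for members that vary together. Muscle genes had a mean correlation of 0.412 within groups, so the preset p-values of that list are likely too small. For the other lists this mean was not computed, and their preset p-values may be too small as well. By fry the lists called were 17 for LIF against NGAL, 16 for NGAL against ANX, 0 for NGAL against control and 12 for uninduced day 2; with the mean of probe sets they were 7 for NGAL against control and 11 for uninduced day 2. Of 93 list calls 26 were lost without at least 1 array, and 17 score differences moved by over 1.5 times. Of the 93 calls 89 were kept with the covariate, 86 after quantile normalization, 84 with the stricter filter, 89 without filter, 89 with the mean of probe sets, 92 with the block and 77 by fry. Of the 67 that low 3'/5' arrays allow, 59 were kept and 8 lost: proximal tubule in LIF and ANX and endothelium, TGF-beta targets and hypoxia in NGAL cultures on day 7, proliferation for LIF against NGAL, and neuron and muscle genes for LIF against ANX. Values that changed sign were Wnt4 for LIF against control on day 2 only (-0.21), Robo2 (-0.019) and Sox17 (-0.55) for LIF against NGAL on days 1 and 2, and Hbg1 for NGAL against ANX on days 5 and 7 (-0.021); the cause was not tested. The lowest array signal sets a floor near which changes of genes under the threshold cannot be read.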

Other observations

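The lists not yet described were not called. Ureteric bud and collecting duct genes were called in 0 of 11 comparisons by camera (smallest adjusted p = 0.149, for NGAL against control), and Ret, the receptor of the bud tip, stayed between log2 5.92 and 6.32 in all groups, near the threshold of 5.79. One gene of that list, Emx2, rose by at least 2.70 from day 1 to day 7 in ANX cultures, from below the threshold to a mean level of 8.49; developing nephron epithelia also express it. Cartilage genes were called in 0 of 11 comparisons as well (smallest adjusted p = 0.127, for uninduced day 1 against fresh, median -0.30), with Col2a1 at 11.13 in fresh tissue and 8.22 in NGAL cultures on day 7. In the self-contained test 32 further list calls appeared and 16 of 93 were lost.

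The course of single genes, chosen after their values were seen, follows. Pax8 stood at 8.69 in fresh tissue and at 6.95 after 1 uninduced day and at 9.26 in LIF, 9.21 in ANX and 8.26 in NGAL cultures on that day; by day 5 it was at 10.40, 10.43 and 10.11. Epcam stood at 7.18 on day 3 in LIF cultures against 5.81 in ANX and 5.26 (below the threshold) in NGAL cultures. On day 7 it was at 8.99, 9.96 and 8.95. Hbe1 was at 7.06 in LIF and 5.92 in ANX cultures on day 4, against 8.89 in NGAL cultures. On day 5 it was below the threshold, at 4.82, 4.92 and 5.11. Slc12a1, the sodium-potassium-chloride transporter of the thick ascending limb, stood at 6.30 in LIF and 7.05 in ANX cultures on day 7. Its levels on day 5 (3.48, 3.40 and 3.47 in LIF, NGAL and ANX cultures) were below the threshold. So was its level of 5.45 in NGAL cultures on day 7, and the size of its rise cannot be read. Its call in ANX cultures ended in 3 of the 4 fits without 1 array.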
